A study of Mus musculus with 13 samples.

How the data were processed

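Total RNA of mouse tail tissue with lymphedema was sequenced in 13 samples, 7 labelled TNTSham and 6 labelled TNTProx1, all at day 28 after TNT and at an age of 12 weeks. Per the labels' protocols, ribosomal RNA was removed and stranded paired-end libraries were sequenced on a NextSeq instrument. The deposited table held raw counts per gene for every sample. Per the submitters' processing notes, reads were trimmed with fastp 0.20.1, aligned to the mouse genome build GRCm39 with HISAT2 2.2.1 and counted per gene with featureCounts of Subread 2.0.2. The same notes name DESeq2 1.34.0 under R 4.1.2 for the submitters' own comparison, whose results were not used here. The strand setting of the counting, the annotation release and the treatment of reads that align to several places are not given in the sources used here. Values of genes with close copies, such as Ccl21a, Skint2, Clca3a2, the histone genes and the mitochondrially encoded genes, which have nuclear copies, are therefore uncertain in that respect. Counts on Prox1 hold reads that align to the mouse gene, and the sequence of any delivered construct is not given in the sources used here.

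The table had 55357 genes, of which 52081 matched an entry of the GENCODE M21 annotation by identifier and 3276 did not. This annotation belongs to an older genome build than the counts. It was used for gene symbols, gene classes, transcript length and GC content only. All 13 columns matched a sample. No pair of libraries was identical, and Spearman correlations between libraries lay between 0.925 and 0.992.

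Counts were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with the group as design, which left 22876. The groups were compared with the quasi-likelihood F test on a model with the group alone. The common dispersion was 0.131, a biological coefficient of variation of 0.362. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold. CPM in the text are TMM-scaled counts per library, fold changes are TNTProx1 over TNTSham, and the median log2 fold change of all tested genes was -0.017. Prox1 was also tested by an exact permutation of log2(CPM + 0.5). Principal components were computed from log2 CPM, with a prior count of 2, of the 1000 most variable genes.

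The comparison, the tests, the alternatives, 36 gene lists and the rule for naming genes were set before the data were examined. The lists held 637 genes, of which 636 were in the table and 618 were tested. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. Members are also given adjusted over the list alone, that is, with p adjusted among the tested members of that list. The rule named Prox1, 15 study genes, the 12 genes of largest change among those that passed in each direction or, as too few passed, the 5 genes of smallest p in each direction with a mean log2 CPM above 0, and the 3 members of smallest p in the direction of each called list. Members outside this rule that the text names, such as Flt1, Thy1, Bmal1, Npas2, Dbp, Tef and Hlf, were chosen after their values were seen. For 1 list, a member that the rule named is not reported here. Also chosen after the data were seen was a list of 17 osteoclast genes in the closing section.

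The alternatives were the Wald test of DESeq2 1.42.0, its size factors or upper quartile scaling in edgeR, no low-count filter, at least 1 CPM in 6 libraries, robust quasi-likelihood, limma voom with quality weights, limma trend and a log2 fold change of at least 1. Further fits had a skeletal muscle score or 1 surrogate variable (sva 3.50.0) as a covariate, or left out each library in turn. The directional fry test was run on the lists. Added after seeing the data were a fit without TNTProx1 4 to 6, a fit with the log2 share of counts on TEC genes as a covariate, and a fit on protein-coding genes. A fit with sex as a covariate was planned only if both sexes were in both groups, which was not so. The group comparison was refitted on 100 splits of the 13 libraries into 7 and 6, the real split included, and with DESeq2 on 40.

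The tests were run on simulated counts with the dispersions of these data, in which 200 of 22876 genes were changed, 50 at each fold. The edgeR test recovered 12, 28, 41 and 44 of 50 genes at folds of 1.5, 2, 3 and 4 and called 3 unchanged genes. DESeq2 recovered 22, 31, 44 and 46 and called 38 unchanged genes. Limma voom with quality weights recovered 9, 27, 39 and 42 and called 1 unchanged gene, and limma trend recovered 12, 27, 42 and 43 and called 4. With no changed gene the edgeR test called 0. A simulated list of 20 genes shifted by 0.5 had a camera adjusted p of 2.19e-22, or 1.14e-05 with an estimated correlation, and 0 of 35 unshifted lists were called. Simulated genes were drawn independently of each other and without any set of libraries standing apart. These counts therefore cannot show how the tests behave where genes vary together, above all camera at the preset correlation.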

Results

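Gene expression was measured by sequencing ribosome-depleted total RNA from mouse tail tissue with lymphedema, a swelling caused by failed lymphatic drainage. The labels place all 13 samples at day 28 after TNT and at an age of 12 weeks. TNT is taken here to be tissue nanotransfection, a way of moving nucleic acids into skin with a short electric field. There were 7 samples in the sham group (TNTSham) and 6 in the group named for Prox1 (TNTProx1). Prox1 encodes the homeobox transcription factor that sets lymphatic endothelial identity. The total count per library was 36.7M ± 6.33M (SD, n = 7) in TNTSham and 40.4M ± 5.08M (SD, n = 6) in TNTProx1, within a range of 29.7M to 48.0M (M, mega). Samples are named by group and replicate number, and the numbers pair nothing across groups. The labels do not say whether samples of a group came from separate animals, so p-values of single genes measure the spread between these samples. Camera p-values at the preset correlation set a list's genes against the other genes. They do not estimate how the list as a whole varies between samples.

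The libraries TNTProx1 4, 5 and 6 stood apart from the other 10 on the first principal component, which held 69.6% of the variance of the 1000 most variable genes. Their share of counts on TEC genes, provisional gene models that are often unspliced, was 0.136 to 0.193%, against 0.378 to 0.745% in the other 10. Malat1, an abundant RNA kept in the nucleus, stood at 3410 to 3539 CPM (counts scaled to library size) in them and at 8979 to 16810 CPM elsewhere. Histone genes took 0.103 to 0.132% of their counts, against 0.0166 to 0.0371% in the other 10. No TNTSham library fell into this set, so within the larger set the comparison is 7 TNTSham libraries against TNTProx1 1, 2 and 3. Values from that comparison of 10 libraries, chosen after seeing the data, are given beside the main ones. Xist was counted at 1990 CPM in TNTSham 1 and at 2.07 CPM or less in the other 12, and TNTSham 1 had no counts on Ddx3y or Uty.

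**Figure D1:**
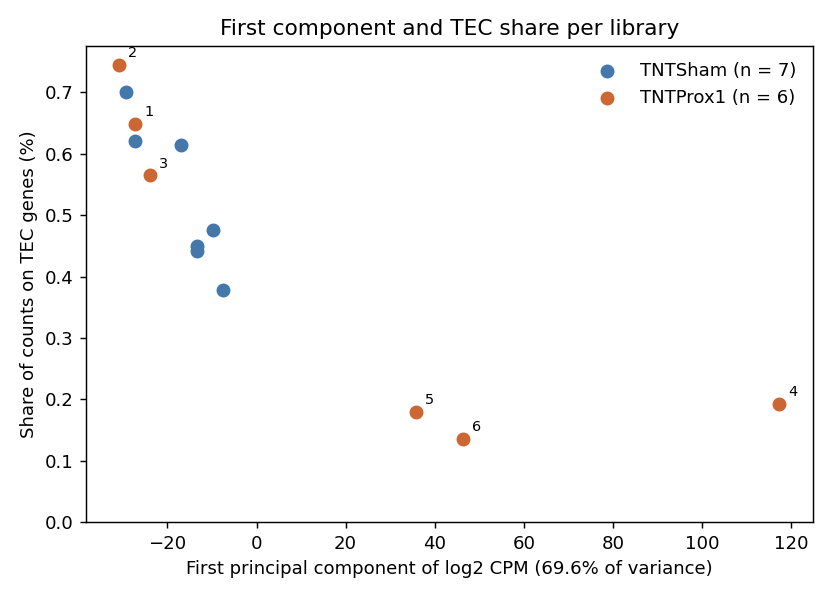
Each point is a library, placed by its score on the first principal component of log2 CPM and by its share of counts on TEC genes in percent; colours give the group and digits the TNTProx1 replicate. TNTProx1 4, 5 and 6 lie at component scores of 35.7 to 117.4 with TEC shares of at most 0.193%, and the other 10 libraries lie at scores of -30.8 to -7.6.

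The series compares TNTProx1 with TNTSham tail tissue. Blood endothelial, matrix and matrix metalloproteinase genes stood higher in TNTProx1, and mitochondrially encoded, skeletal muscle and clock genes stood lower. Camera called these 6 lists at its preset correlation, and none of them with an estimated correlation (adjusted p = 0.0767 to 0.346 with an estimated correlation). Of 100 splits of the libraries, 20 gave a skeletal muscle median at least as far from 0, against 1 to 3 for the other lists named here. The 5 named genes with the smallest p among those higher were Tgfb1, Fscn1, Slc13a3, Egfl7 and Ctsk. The 5 among those lower were Alox12e, Skint2, Clca3a2, Per2 and Id4. For each of these 10 genes all 6 TNTProx1 libraries lay outside the TNTSham range. The genes were picked by their p-values in these same libraries, so this separation is no separate evidence.

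No single gene passed the test over all genes. The edgeR quasi-likelihood test called 0 of 22876 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.0848, shared by 33 genes. At an unadjusted p under 0.05 there were 2802 genes, 1905 of them higher and 897 lower in TNTProx1. By chance 1144 are expected on average if no gene differs, and where genes vary together a single count can lie far from that. The 26 other splits of the libraries that kept TNTProx1 4 to 6 on the same side had a median of 2131.5, and 8 of 100 splits gave as many as 2802. The DESeq2 Wald test called 561 differentially expressed genes, 410 higher and 151 lower, limma voom with quality weights called 573 and limma trend called 0. Histone genes were among the 410. As a class they took 0.103 to 0.132% of counts in TNTProx1 4 to 6 and 0.0189 to 0.0344% in TNTProx1 1 to 3. The share in TNTSham was 0.0166 to 0.0371%. These histone calls therefore follow the split of the libraries and not the group as a whole. DESeq2 called each of the 10 genes of smallest p named above, on the same counts that picked them, so this is no independent check. Without TNTProx1 1 the edgeR test called 589 genes, without TNTSham 5 it called 34, and with 10 libraries, TNTProx1 4 to 6 left out, it called 0 with 5116 genes at unadjusted p under 0.05. With the TEC share as a covariate, a fit chosen after seeing the data, it called 545 genes, and with the skeletal muscle covariate 38.

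Of these 10 genes, Tgfb1 (ENSMUSG00000002603.16), a central profibrotic cytokine, had a mean of 39.6 ± 5.25 CPM (SD, n = 7) in TNTSham and 62.2 ± 8.28 CPM (SD, n = 6) in TNTProx1. Its log2 fold change was 0.65 ± 0.11 (SE; edgeR adjusted p = 0.0848). Ctsk (ENSMUSG00000028111.5), the collagen-degrading protease cathepsin K, went from 451 ± 96.9 CPM to 828 ± 138 CPM, a log2 fold change of 0.88 ± 0.15 (SE). Fscn1, an actin-bundling protein, had a log2 fold change of 0.84 ± 0.14, and Egfl7, an endothelial secreted factor, of 0.64 ± 0.11. Slc13a3, a dicarboxylate transporter, went from 3.79 ± 1.14 CPM to 10.1 ± 3.72 CPM. Alox12e (ENSMUSG00000018907.11), an epidermal lipoxygenase, stood at 71.8 ± 53.4 CPM in TNTSham and 10.4 ± 2.98 CPM in TNTProx1, a log2 fold change of -2.79 ± 0.42 (SE). Skint2 had a log2 fold change of -3.15 ± 0.52, Clca3a2 of -1.78 ± 0.31 and Id4, a helix-loop-helix inhibitor, of -0.48 ± 0.10. Skint2 and Clca3a2 belong to families of similar genes, and how reads shared within a family were counted is not given in the sources used here.

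Prox1 (ENSMUSG00000010175.14) was the gene named in the group label. Its level was 26.7, 28.9, 29.5, 23.4, 27.7, 27.6 and 33.1 CPM in TNTSham 1 to 7. It was 42.8, 72.9, 29.6, 18.7, 28.5 and 32.6 CPM in TNTProx1 1 to 6. The means were 28.1 ± 2.95 CPM (SD, n = 7) and 37.5 ± 19.0 CPM (SD, n = 6), so 2 TNTProx1 libraries lay above the TNTSham range and 1 below it. The log2 fold change of 0.41 ± 0.23 (SE) had an edgeR adjusted p of 0.506, and without TNTProx1 2 it was 0.11. An exact two-sided permutation test of log2(CPM + 0.5) over the 1716 splits gave a difference of 0.29 with p = 0.307. With 10 libraries the log2 fold change was 0.78 ± 0.20 (SE) and the adjusted p 0.0747.

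Lymphatic endothelial markers stood higher in TNTProx1 as a list. Of the 20 members 16 were higher, at a median log2 fold change of 0.29, and camera called the list (adjusted p = 0.000319). The call was lost with an estimated correlation (adjusted p = 0.257 with an estimated correlation), and 0 members passed adjusted over the list alone (3 without TNTProx1 5). Pdpn, the membrane glycoprotein podoplanin, had a log2 fold change of 0.53 ± 0.16 (SE), the valve transcription factor Foxc2 of 0.72 ± 0.22 and the integrin subunit Itga9 of 0.34 ± 0.13. Lyve1, a hyaluronan receptor, went from 80.6 ± 20.2 to 122 ± 52.3 CPM, and Flt4, the receptor of Vegfc, from 52.3 ± 4.88 to 71.1 ± 32.3 CPM. Without TNTProx1 2 the log2 fold change of Flt4 was 0.15, against 0.44 with all 13 libraries, and that of Itga9 was 0.22. Ccl21a, a chemokine of lymphatic vessels with near-identical copies, had a log2 fold change of 0.07 ± 0.28. Without TNTProx1 2 the list's median was 0.12, and with 10 libraries it was 0.47 with 9 members passing adjusted over the list alone, Flt4 at 0.68 and Itga9 at 0.54.

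Lymphangiogenic growth factors and receptors were also called higher (median 0.22; 24 of 26 members higher; camera adjusted p = 5.13e-07, and adjusted p = 0.121 with an estimated correlation). Tie1, an endothelial receptor tyrosine kinase, Ephb4, a venous ephrin receptor, and Pdgfb, a pericyte-recruiting growth factor, passed adjusted over the list alone. Their log2 fold changes were 0.82 ± 0.14, 0.39 ± 0.10 and 0.61 ± 0.19 (SE). The number passing was 1 without TNTSham 1 and 7 without TNTProx1 4. Vegfc, the main lymphatic growth factor, had 6.61 ± 0.818 CPM in TNTSham and 8.38 ± 1.29 CPM in TNTProx1 (log2 fold change 0.34 ± 0.14, adjusted p = 0.326). Vegfd had a log2 fold change of 0.01 ± 0.20, whose sign turned in several other fits. The list's median was 0.35 with 10 libraries, and the value of Ephb4 0.24 ± 0.11. This list shares Flt4 and Nrp2 with the lymphatic endothelial list, which also holds Prox1. It shares Tie1 and Kdr with the blood endothelial list, so the calls of these lists are not separate evidence.

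**Figure D2:**
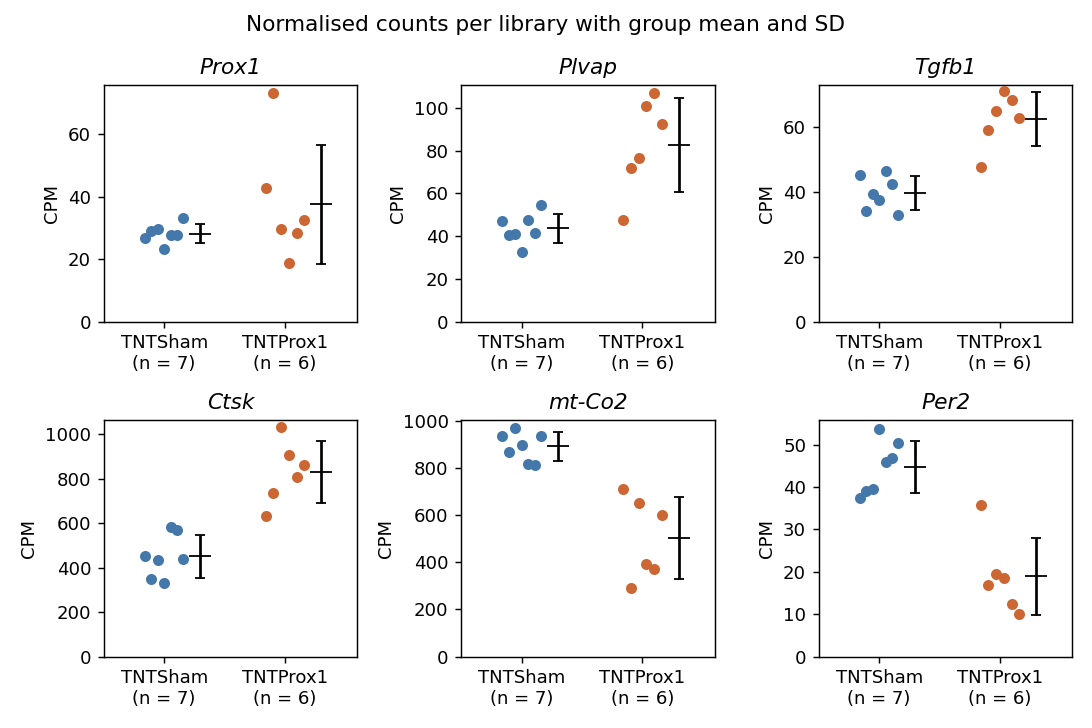
CPM of 6 genes in each library, with the group mean and SD as a bar beside the 7 TNTSham and 6 TNTProx1 points. All 6 TNTProx1 libraries lie above every TNTSham library for Tgfb1 and Ctsk and below every one for mt-Co2 and Per2, 5 of 6 lie above for Plvap, and 2 of 6 for Prox1.

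Blood endothelial markers stood higher in TNTProx1 at a median log2 fold change of 0.51, with 17 of 18 members higher. Of these members 13 passed adjusted over the list alone and 0 passed over all genes. Plvap, a component of vessel fenestrae, went from 43.7 ± 6.91 CPM (SD, n = 7) to 82.7 ± 22.0 CPM (SD, n = 6), a log2 fold change of 0.92 ± 0.17 (SE; edgeR adjusted p = 0.0848). Egfl7 and Tie1 were the other members with the smallest p. Flt1, a Vegfa receptor, was the member that went the other way (-0.42 ± 0.27), and Vwf, Sox17, Ptprb and Erg, at 0.09 to 0.41, did not pass over the list either. Camera called the list at an adjusted p of 2.97e-16, with an adjusted p of 0.0767 with an estimated correlation. The median was 0.56 with 10 libraries, and the value of Plvap 0.58 ± 0.16.

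Smooth muscle and pericyte markers, which cover the vessel wall, were called higher with 13 of 14 members higher and a median of 0.28. The list had a camera adjusted p of 0.00215 and an adjusted p of 0.341 with an estimated correlation. Kcnj8, a pericyte potassium channel subunit, passed adjusted over the list alone (log2 fold change 0.87 ± 0.18 SE). Pdgfrb and Rgs5 had log2 fold changes of 0.41 ± 0.17 and 0.39 ± 0.18, and Acta2, smooth muscle actin, of 0.40 ± 0.24. Without TNTProx1 6 the list's median was 0.16 and the value of Rgs5 0.21, and without TNTSham 1 that of Acta2 was 0.63. With 10 libraries the list's median was 0.09 and camera did not call it (adjusted p = 0.271), with Acta2 at 0.00 and Rgs5 at 0.13.

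Genes of fibrosis and extracellular matrix were higher in TNTProx1 in 29 of 29 members, at a median log2 fold change of 0.39. Of these, 7 passed adjusted over the list alone: Tgfb1, Serpinh1, P4ha1, Lox, Loxl1, Sparc and Cthrc1. Serpinh1, a collagen chaperone, went from 240 ± 49.8 CPM (SD, n = 7) to 433 ± 126 CPM (SD, n = 6), and P4ha1, a collagen prolyl hydroxylase subunit, from 56.2 ± 9.11 to 79.0 ± 7.23 CPM. Col1a1, the main chain of type I collagen, had a log2 fold change of 0.64 ± 0.31 (SE, adjusted p = 0.429) and Col3a1 of 0.36 ± 0.19 (adjusted p = 0.463), against 0.29 and 0.20 without TNTProx1 3. Camera called the list (adjusted p = 1.2e-14, and adjusted p = 0.132 with an estimated correlation). The number passing was 11 without TNTSham 5, and with 10 libraries the median was 0.53 and the value of Serpinh1 0.50 ± 0.18.

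Matrix metalloproteinases, enzymes that cut matrix proteins, were higher in 11 of 11 tested members, at a median of 0.54. Mmp9, a gelatinase, went from 168 ± 85.7 CPM (SD, n = 7) to 470 ± 160 CPM (SD, n = 6), a log2 fold change of 1.49 ± 0.32 (SE). Mmp3, a stromelysin, and Mmp19 had log2 fold changes of 0.90 ± 0.28 and 0.47 ± 0.13. These 3 with Mmp13 and Mmp14 were the 5 members that passed adjusted over the list alone, against 2 without TNTProx1 3. Camera called the list at an adjusted p of 4.02e-08, with an adjusted p of 0.0767 with an estimated correlation, and the median with 10 libraries was 0.64. Mmp9 and Ctsk also belong to a list of 17 osteoclast genes, chosen after the data were seen, of which 17 were higher at a median of 0.88. Mmp9 and the osteoblast gene Sp7 were both lowest in TNTSham 4 (67.7 and 5.46 CPM) and highest in TNTProx1 3 (746 and 42.3 CPM). Mmp3 and Mmp19 were highest in TNTProx1 1 (258 and 53.7 CPM). Whether the samples held bone is not given in the sources used here. A differing share of bone was not tested for this list or the matrix list.

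Cartilage and bone markers were called higher as well, with 16 of 17 members higher, a median of 0.50 and no member passing adjusted over the list alone. Sp7, an osteoblast transcription factor, went from 15.4 ± 7.02 to 30.2 ± 8.63 CPM, Col11a2 from 65.6 ± 24.2 to 126 ± 60.3 CPM and Comp, a cartilage matrix protein, from 158 ± 24.7 to 202 ± 29.3 CPM. Its camera adjusted p was 2.32e-07, with an adjusted p of 0.209 with an estimated correlation. The median was 0.81 with 10 libraries, and without TNTSham 5 there were 5 members passing.

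Mitochondrially encoded transcripts stood lower: 15 of 15 were lower in TNTProx1, at a median log2 fold change of -1.11, and all 15 passed adjusted over the list alone. Together, mitochondrially encoded genes took 1.78 ± 0.258% of counts in TNTSham (SD, n = 7) and 0.963 ± 0.239% in TNTProx1 (SD, n = 6). The cytochrome oxidase subunit mt-Co2 went from 891 ± 61.9 to 503 ± 173 CPM, a log2 fold change of -0.82 ± 0.19 (SE), mt-Atp6 had -1.11 ± 0.25 and mt-Cytb -0.91 ± 0.23. In camera the adjusted p was 6.85e-18, with an adjusted p of 0.0913 with an estimated correlation. With 10 libraries the median was -0.87 and 9 members passed adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes were not called, with a median of 0.12 and an adjusted p of 0.447. With 10 libraries they were called lower at a median of -0.32.

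Skeletal muscle markers were lower in 21 of 22 members at a median of -0.50, and Myh1, Myh2, Tnnc2, Ttn and Neb passed adjusted over the list alone. Tnnc2, fast troponin C, had 24.7 ± 13.1 CPM in TNTSham (SD, n = 7) and 10.3 ± 2.47 CPM in TNTProx1 (SD, n = 6). Neb, the thin filament protein nebulin, had a log2 fold change of -0.81 ± 0.22 (SE) and Myh2, a fast myosin heavy chain, of -0.73 ± 0.22. Camera called the list lower (adjusted p = 3.46e-07, and adjusted p = 0.346 with an estimated correlation). With 10 libraries the median was -1.12 and 19 members passed. Without TNTProx1 2, the library with the lowest muscle score, no member passed. The score, a scaled mean of the list's members, was -0.62, -2.26 and -0.94 in TNTProx1 1 to 3. In TNTProx1 4 to 6 it was 0.24 to 0.28, within the TNTSham range of -0.54 to 1.69. With the muscle score as a covariate, the median of the mitochondrially encoded list was -1.28 and that of the blood endothelial list 0.44.

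Circadian clock genes stood lower as a list, at a median of -0.47 with 13 of 16 members lower and 11 passing adjusted over the list alone. Per2, a repressor of the clock, went from 44.7 ± 6.17 CPM (SD, n = 7) to 18.9 ± 9.04 CPM (SD, n = 6), a log2 fold change of -1.24 ± 0.23 (SE; edgeR adjusted p = 0.0848). Ciart and Cry1, also repressors, had -1.11 ± 0.25 and -0.50 ± 0.12, and the output genes Dbp, Tef and Hlf -0.63 ± 0.25, -0.52 ± 0.13 and -0.80 ± 0.22. Npas2, a partner of the clock activator Bmal1, went the other way with a log2 fold change of 1.37 ± 0.29 and passed adjusted over the list alone. Bmal1 had 0.49 ± 0.30. The camera adjusted p was 4.3e-07, with an adjusted p of 0.0767 with an estimated correlation, and the median was -0.38 with 10 libraries.

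Neutrophil and acute inflammatory genes stood higher at a median of 0.90, with 20 of 22 members higher and Nos2 alone passing adjusted over the list alone. Nos2, inducible nitric oxide synthase, went from 3.49 ± 2.30 to 9.89 ± 2.63 CPM, a log2 fold change of 1.5 ± 0.33 (SE). Saa3, an acute phase protein, had 1.32 ± 0.46 and the monocyte chemokine Ccl2 0.56 ± 0.21. Camera gave an adjusted p of 6.92e-08, and an adjusted p of 0.255 with an estimated correlation. The number passing was 12 without TNTSham 6, and with 10 libraries it was 6 at a median of 0.99.

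Macrophage markers were called higher, with 17 of 19 members higher and a median of 0.39 (camera adjusted p = 7.68e-06, and adjusted p = 0.148 with an estimated correlation). The Fc receptor Fcgr1 had a log2 fold change of 0.73 ± 0.22 (SE) and the scavenger receptor Msr1 of 0.50 ± 0.17. Marco, another scavenger receptor, had 1.8 ± 0.61 at means of 0.172 and 0.608 CPM. Adgre1, the F4/80 antigen, had 0.29 ± 0.19, or 0.48 without TNTSham 1. None passed adjusted over the list alone, against 9 members without TNTSham 1 and 5 with 10 libraries at a median of 0.30. Complement genes were called higher, with 12 of 16 members higher, a median of 0.23 and C1ra, Cfp and C5ar1 passing adjusted over the list alone. Their log2 fold changes were 0.30 ± 0.09, 0.72 ± 0.20 and 0.61 ± 0.16. The camera adjusted p was 0.000476, with an adjusted p of 0.168 with an estimated correlation, and the number passing was 0 without TNTSham 2 and 7 without TNTSham 1. The median with 10 libraries was 0.21.

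Immediate early and heat shock genes were called higher at a median of 0.26, with 13 of 16 members higher and Fos and Junb passing adjusted over the list alone, against 6 members without TNTProx1 2 and 5 without TNTProx1 1. No member passed without any 1 of TNTSham 1, 2, 3, 4, 5 or 7 or TNTProx1 3, 4 or 5, and 1 passed without TNTProx1 6. Junb went from 19.4 ± 7.28 to 48.6 ± 31.2 CPM, Fos had a log2 fold change of 0.78 ± 0.23 and Jund of 0.74 ± 0.26. The camera adjusted p was 0.00215, with an adjusted p of 0.346 with an estimated correlation. The list was not called with 10 libraries (camera adjusted p = 0.737, median 0.04), where Junb had 0.33 ± 0.34 and Jund -0.04 ± 0.18. Interferon-stimulated genes were called higher with 21 of 25 members higher and a median of 0.28 (camera adjusted p = 0.00284, and adjusted p = 0.691 with an estimated correlation). Bst2 had 0.61 ± 0.19, Cxcl9 1.29 ± 0.46 and Irf7 0.69 ± 0.30. Over the alternative fits Cxcl9 lay at 0.44 to 1.64 and Irf7 at 0.32 to 0.83. Leaving out TNTProx1 2 gave a median of 0.04 and a camera adjusted p of 0.548, and the 10-library median was 0.47.

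T cell markers were called lower, with 16 of 20 members lower and a median of -0.39. Icos, a costimulatory receptor, had a log2 fold change of -0.97 ± 0.24 (SE) and passed adjusted over the list alone, while Thy1, also a fibroblast antigen, passed in the other direction (5 members passed without TNTSham 5). Cd3g and Ctla4 had -0.89 ± 0.31 and -0.76 ± 0.29, and Cd4 had -0.01 ± 0.25, or 0.25 with 10 libraries. In the camera test the adjusted p was 0.0197, with an adjusted p of 0.673 with an estimated correlation. The call was lost without TNTSham 1, 4 or 7 and without TNTProx1 1 or 3, at adjusted p of up to 0.201, and the 10-library median was -0.55. Helper T subset cytokines and regulators were called lower in 10 of 14 tested members at a median of -0.32. The camera adjusted p was 0.0135, with an adjusted p of 0.341 with an estimated correlation. Their call was lost without TNTSham 1, TNTProx1 2 or TNTProx1 3, at adjusted p of up to 0.0629, and the 10-library median was -0.42. Ccl22, a chemokine that attracts T cells, had -0.73 ± 0.22 and Ccr4, a chemokine receptor, -1.09 ± 0.38, or -1.76 with 10 libraries, and without TNTProx1 6 there were 4 members that passed adjusted over the list alone. Il4, Il13 and Ifng, at group means of 0.328 CPM or less, did not pass the low-count filter with 13 libraries. With 10 libraries Il4 passed it, at a log2 fold change of -1.01 ± 0.59 (edgeR adjusted p = 0.351).

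Differentiated keratinocyte markers were called lower, with 19 of 20 members lower and a median of -0.33. Krt77, Sbsn and Krt2, proteins of the upper epidermis, had log2 fold changes of -0.78 ± 0.27, -0.60 ± 0.24 and -0.66 ± 0.30 (SE). Camera called them at an adjusted p of 8.34e-05, with an adjusted p of 0.558 with an estimated correlation. The call was lost without TNTProx1 2, at a median of -0.13 and a camera adjusted p of 0.05 after rounding. Without TNTProx1 6 the median was -0.63 with 4 members passing, and with 10 libraries the median was -0.92 with 14 members passing adjusted over the list alone. Cholesterol synthesis genes were called lower in 18 of 19 members at a median of -0.18, and Pmvk, phosphomevalonate kinase, passed adjusted over the list alone (-0.53 ± 0.13), but not without TNTSham 2 or without TNTProx1 2. Fdft1 and Hmgcs1 had -0.39 ± 0.18 and -0.33 ± 0.19, against -0.26 and -0.21 without TNTProx1 2, and Hmgcs1 had -0.20 without TNTSham 7. Camera gave 0.00663 as the adjusted p, with an adjusted p of 0.737 with an estimated correlation. The call was lost without TNTSham 7, TNTProx1 1 or TNTProx1 2, at adjusted p of up to 0.392. With 10 libraries the median was -0.66 and 18 members passed, with Fdft1 at -0.76 and Hmgcs1 at -0.65.

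Cell cycle genes were called higher with 21 of 24 members higher and a median of 0.30 (camera adjusted p = 0.000476, and adjusted p = 0.691 with an estimated correlation). Aurka, Ccnb2 and Ccna2 had log2 fold changes of 0.46 ± 0.21, 0.54 ± 0.26 and 0.48 ± 0.23 (SE), and no member passed adjusted over the list alone. The list was not called with 10 libraries (median -0.08, camera adjusted p = 0.271), where Aurka, Ccnb2 and Ccna2 had 0.02, -0.19 and -0.06.

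The other lists were not called with 13 libraries. Their adjusted p was 0.0825 for hypoxia and glycolysis and 0.155 for basal keratinocyte markers. It was 0.447 for leukotriene and prostaglandin synthesis and for markers of B and plasma cells, tendon, dendritic cells and antigen presentation, and hair follicle. It was 0.461 for Schwann cell and nerve markers, 0.521 for sebaceous gland and lipid synthesis genes and 0.651 for wound-activated keratinocyte genes. It was 0.685 for mast cell markers and for ribosomal protein genes, 0.747 for adipocyte, 0.831 for melanocyte and 0.877 for erythrocyte markers. In 3 of these, wound-activated keratinocyte, ribosomal protein and adipocyte genes, the median lay above 0 while camera gave the direction as lower. With 10 libraries basal keratinocyte, wound-activated keratinocyte, hair follicle, sebaceous gland, hypoxia and ribosomal protein genes were called lower, the ribosomal list at a median of -0.59 and the wound-activated list at -0.86. Across protein-coding genes, the Spearman correlation of the group log2 fold change with transcript length was -0.15 with 13 libraries and 0.25 with the 10.

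Over all lists, camera with the preset correlation called 20 of 36, 13 higher and 7 lower, and 0 with an estimated correlation. Other splits of the libraries called nearly as many at the preset correlation. The median was 16 lists in the 26 that kept TNTProx1 4 to 6 on the same side. It was 17 in the 73 that parted them. A call at the preset correlation therefore does not by itself set the real groups apart from other groupings. The directional fry test, which asks whether a list's own genes move one way, called 6. These were the mitochondrially encoded, blood endothelial, matrix, matrix metalloproteinase, clock and lymphangiogenic lists (fry adjusted p = 0.00994 to 0.0363). The blood endothelial and lymphangiogenic lists share Tie1 and Kdr. Skeletal muscle markers were not called by fry (adjusted p = 0.18). The 10-library comparison, which shares all its libraries with the main one, called 17 of the 20 lists in the same direction and 7 other lists. Of 618 list genes tested, 0 passed over all genes, and 69 list memberships passed adjusted over the list alone. That number was 206 with 10 libraries, 202 with the TEC share covariate and 165 with 1 surrogate variable. These fits are not separate checks, since each sets TNTProx1 4 to 6 apart. The surrogate variable was 0.785, 0.244 and 0.31 in TNTProx1 4, 5 and 6 and negative in every other library. The TEC share was lowest in the same libraries.

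**Figure D3:**
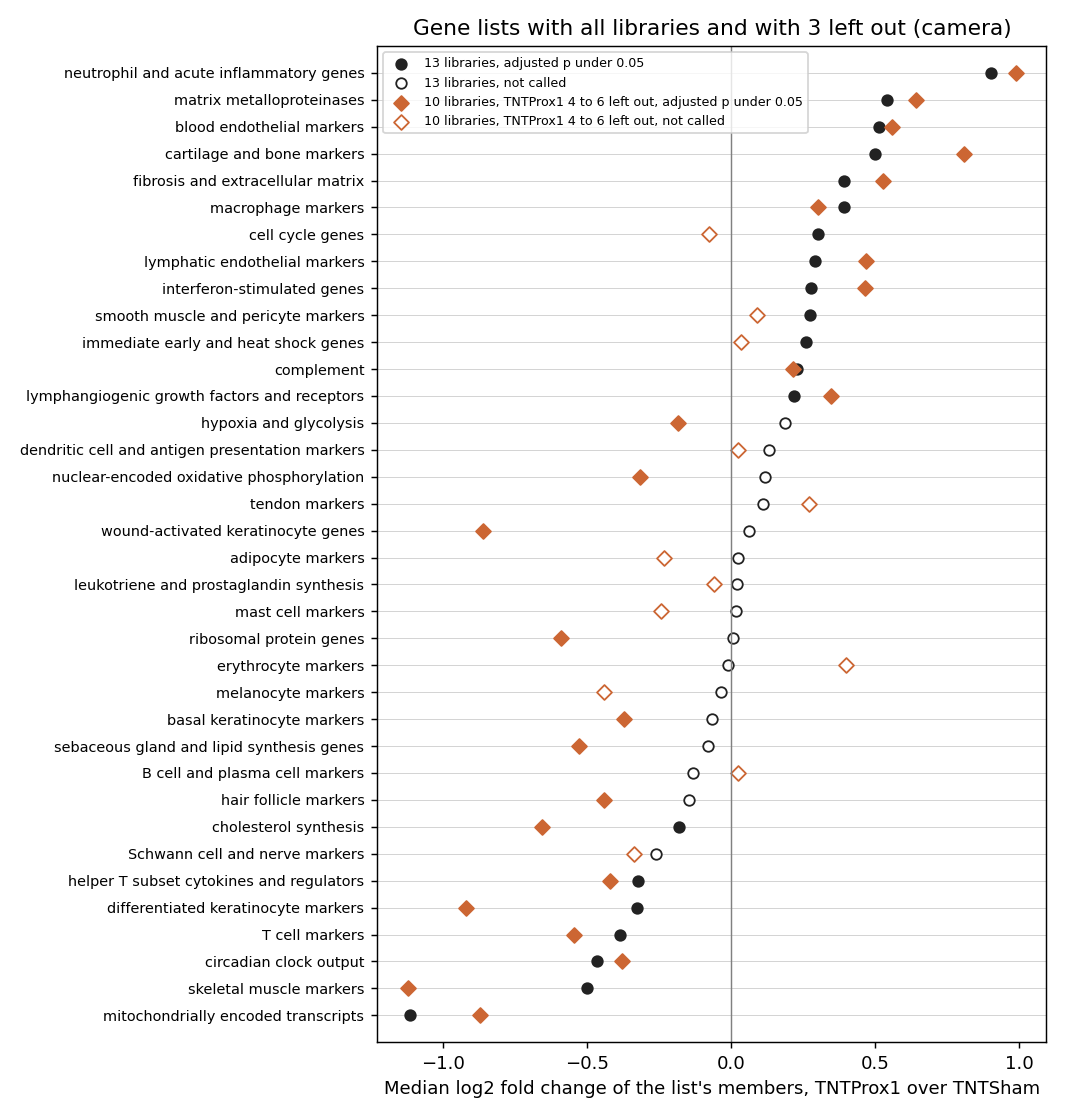
Median log2 fold change of the members of each of 36 lists, TNTProx1 over TNTSham, with all 13 libraries (circles) and with TNTProx1 4 to 6 left out (diamonds); filled symbols are lists that camera called with the preset correlation. The blood endothelial list lies at 0.51 and 0.56 and the mitochondrially encoded list at -1.11 and -0.87, while the ribosomal protein list moves from 0.01 to -0.59.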

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

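The tests of depth, antisense genes, splits that keep TNTProx1 4 to 6 together, the muscle covariate, the left-out libraries and the time of day were chosen after the result was seen, and the test of transcript length after the split of the libraries was seen but before its value was known.

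In 14 of 178 sets of values within a group, a library lay far from the others of its group, where chance gives about 1 in 20, or 9. TNTSham 1 held Vegfd at 71.3 CPM (31.8 to 40.5 in the other TNTSham libraries), Adgre1 at 115 CPM (51.3 to 64.0), Cfp at 34.7 CPM (12.8 to 18.6) and Xist at 1990 CPM (0.258 to 2.07). TNTSham 6 held mt-Atp6 at 471 CPM (960 to 1350), mt-Cytb at 813 CPM (1230 to 1680), Fos at 40.8 CPM (17.5 to 22.8) and Pmvk at 17.1 CPM (24.1 to 28.7). Krt77 was at 5.58 CPM in TNTSham 2 (2.89 to 3.70), and Kcnj8 at 8.88 CPM in TNTSham 5 (4.65 to 5.98). Among TNTProx1 libraries, Ephb4 was at 52.9 CPM in TNTProx1 1 (71.3 to 83.9 in the others) and Flt4 at 136 CPM in TNTProx1 2 (48.5 to 68.6). Il13 was at 0.411 CPM in TNTProx1 5 (0 to 0.0777) and Saa3 at 3.57 CPM in TNTProx1 6 (18.4 to 44.1).

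TNTProx1 4 to 6 stood apart from TNTProx1 1 to 3, samples with the same labels. A lower total of counts on genes was excluded, since the lowest of their totals was 42.4M counts against a median of 36.5M in the other 10. The number of reads sequenced was not examined. Genes with a count numbered 24172 to 28807 in TNTProx1 4 to 6 and 27854 to 33986 in the other 10. Less unspliced or nuclear RNA remained open: the median log2 ratio of antisense genes, whose shares had been seen, lay below that of protein-coding genes by a difference of -1.05, and strand assignment in the counting is not given in the sources used here. Transcript length bias remained open too, with a Spearman correlation of -0.40 between the log2 ratio and transcript length over 16015 protein-coding genes. No biological explanation was tested, and no TNTSham library lies in this set. Without it 17 of the 20 called lists were called in the same direction, 3 were not called, and 7 other lists were called. Both comparisons share the other 10 libraries, so this overlap is no independent check.

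Blood endothelial markers stood higher in TNTProx1 at a median of 0.51. The muscle score did not account for the whole of it, since the median was 0.44 with the score as covariate. Less skeletal muscle RNA in TNTProx1 remained open, as the score may not track it in every library. In TNTProx1 4 to 6 the score lay within the TNTSham range, while Ttn took 0.201 to 0.266% of counts, against 0.642 to 1.05% in TNTSham. T cell markers had a median of -0.39, but 17 of 100 splits gave a median as far from 0, so their direction does not decide it. The library split of TNTProx1 4 to 6 was argued against by a median of 0.56 without them. Other differences between libraries were not removed by leaving them out. The Spearman correlation of the group log2 fold change with transcript length was 0.25 with 10 libraries and -0.15 with 13. Of 100 splits of the libraries, 1, the real one, gave a median as far from 0 (0.514, highest other 0.439), and it was also 1 of the 27 that kept TNTProx1 4 to 6 together. The split with 0.439 differed from the real one only in placing TNTSham 6 with the TNTProx1 libraries. The limit of 5% was set for a single list, and for a list picked from 36 the 100 splits are too few to reach it. A larger share of vessel tissue in the samples and a response to the treatment both stay open and were not tested against each other.

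Circadian clock genes stood lower in TNTProx1 at a median of -0.47. The library split of TNTProx1 4 to 6 was argued against by a median of -0.38 without them, though other differences between libraries were not removed. Of 100 splits 1, the real one, gave a median as far from 0 (0.466 in size, highest other 0.387). It was also 1 of the 27 that kept TNTProx1 4 to 6 together. For a list picked from 36 the 100 splits are too few to reach the 5% limit. Another time of day at collection remained open: Bmal1 and Npas2 minus 7 genes of the opposite phase differed by 1.67 between groups, in genes whose directions had been seen. This score was -2.94 to -2.33 in TNTSham and -2.32, -0.03, -0.38, -2.73, -0.13 and 0.10 in TNTProx1 1 to 6, so TNTProx1 1 and 4 lay at or near the TNTSham values. The time of collection is not given in the sources used here, and a change of the clock with treatment stays open, untested.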

How the results depend on the processing

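The fits without TNTProx1 4 to 6, with the TEC share covariate and on protein-coding genes were chosen after the result was seen. The edgeR count of 0 differentially expressed genes (2802 at unadjusted p under 0.05) was 0 with DESeq2 size factors, upper quartile scaling, the 1 CPM filter, robust quasi-likelihood, limma trend, a log2 fold change of at least 1, 1 surrogate variable, protein-coding genes and 10 libraries. It was 561 with the DESeq2 Wald test, 573 with limma voom with quality weights, 1 with no low-count filter, 38 with the skeletal muscle covariate and 545 with the TEC share covariate. With 1 library left out it was 0 to 589 (34 without TNTSham 5, 589 without TNTProx1 1). DESeq2 and voom shared 257 genes. The quality weights of voom were 0.118, 0.33 and 0.296 in TNTProx1 4, 5 and 6, against 0.809 to 2.96 in the other libraries. Voom, the TEC share covariate and the surrogate variable thus all bear on the same libraries. List members called over all genes, 0 in edgeR, were 50 with DESeq2, 51 with voom, 1 with the skeletal muscle covariate, 44 with the TEC share covariate and 0 to 41 with 1 library left out (5 without TNTSham 5, 41 without TNTProx1 1). Gene lists called, 20 with camera, were 0 with camera with an estimated correlation and 6 with fry, and 15 to 24 in the other fits.

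Prox1 kept a positive log2 fold change in every fit, from 0.07 to 0.78, with adjusted p of 0.0747 to 0.870. Vegfd was 0.00 with the DESeq2 Wald test, with DESeq2 size factors and with no low-count filter, -0.06 with voom, -0.20 with the skeletal muscle covariate, -0.01 with protein-coding genes and -0.11 to 0.19 with 1 library left out. Ccl21a was -0.32 with voom, 0.00 with limma trend and -0.23 to 0.20 with 1 library left out. Cd4 was 0.03 with voom, 0.11 with 1 surrogate variable, 0.25 with 10 libraries, 0.12 with the TEC share covariate and -0.19 to 0.14 with 1 library left out. Ccnb2 was -0.01 with voom and -0.19 with 10 libraries, where Ccna2 was -0.06 and Jund -0.04. The medians of skeletal muscle markers (0.15), interferon-stimulated genes (-0.04) and cholesterol synthesis (0.06) turned with the skeletal muscle covariate. With 10 libraries cell cycle genes had a median of -0.08, and immediate early and heat shock genes 0.04 with the camera direction lower. The skeletal muscle result follows from using the muscle score itself as covariate, and for the other changes the cause was not tested. Sex as a covariate was not run, since TNTSham 1 alone expressed Xist.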

Other observations

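The osteoclast genes and the tests on them were chosen after the result was seen, as were the comparison without TNTProx1 4 to 6 and the counts among splits that keep these libraries together.

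Genes of osteoclasts, the cells that resorb bone, stood higher in TNTProx1. Of 17 such genes 17 were higher at a median log2 fold change of 0.88, and 11 passed adjusted over the list alone. Acp5, tartrate-resistant acid phosphatase, went from 88.7 ± 34.4 CPM (SD, n = 7) to 247 ± 74.2 CPM (SD, n = 6), and Atp6v0d2, a proton pump subunit, from 22.1 ± 9.69 to 45.6 ± 9.81 CPM. Dcstamp, needed for cell fusion, had a log2 fold change of 1.27 ± 0.31 (SE), Itgb3 of 0.85 ± 0.20 and Siglec15 of 1.36 ± 0.40. Car2, a carbonic anhydrase, had 0.06 ± 0.38, and -0.87 with 10 libraries. As Acp5, Ctsk, Mmp9 and Ckb had been seen before the list was made, the other 13 were tested alone. All 13 were higher at a median of 0.80, with a camera p of 8.38e-11, or p = 0.0118 with an estimated correlation, and 6 passed. Of 100 splits, 1, the real one, gave osteoclast genes a median as far from 0 (0.802, highest other 0.741). As the real split prompted the list and its genes are expressed together, neither these p-values nor this count says whether chance is excluded. Whether bone was part of the samples is not given in the sources used here.

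The mitochondrially encoded list had a median of -1.11 (1.114 in size, against 1.241 at most in another split). Of 100 splits 2 gave a median as far from 0, the real one included, but these were 2 of the 27 that kept TNTProx1 4 to 6 together, as the real split does (7.4%), so chance was not excluded. The other split differed from the real one only in placing TNTSham 6 with the TNTProx1 libraries, so it was not an unrelated grouping. Of the 20 called lists, 8 had medians matched in fewer than 5 of 100 splits and 12 in 5 or more. Among the 12 were lymphatic endothelial markers (8 of 100), lymphangiogenic factors (7), cartilage and bone (6), smooth muscle and pericyte (8), skeletal muscle (20), T cell (17), helper T (19) and differentiated keratinocyte markers (26). The others were cell cycle (26), immediate early (19), interferon-stimulated (29) and cholesterol synthesis genes (37), and chance was not excluded for any of the 12 over all 100 splits. Among the 27 splits that kept TNTProx1 4 to 6 together, the cartilage and bone list was matched by none but the real one (1 of 27, highest other 0.476 against 0.5). Of the 8, fibrosis and matrix (3 of 27), matrix metalloproteinases (2), neutrophil genes (3) and macrophage markers (2) were, like the mitochondrially encoded list, matched in over 5% of the 27, and blood endothelial, clock and complement lists were not (1 each), which for lists picked from 36 does not exclude chance.

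A count of 0 differentially expressed genes is matched by any split, here 100 of 100 with a highest other of 1218, so this says nothing about chance. For genes at unadjusted p under 0.05, 8 of 100 splits gave as many as the real 2802 (highest other 7182), and for gene lists called 32 of 100 gave as many as 20 (highest other 26), so chance was not excluded for either. For list members passing adjusted over the list alone, 2 of 100 gave as many as 69 (highest other 107), but both were among the 27 that kept TNTProx1 4 to 6 together (7.4%), so chance was not excluded. The limit of 5% had been set over all splits, which mix these with splits that part the 3 libraries. For DESeq2, 2 of 40 gave as many genes as 561 (highest other 4051), so chance was not excluded. The split with 1218, 7182, 107 and 4051 put TNTSham 1 to 3 with TNTProx1 4 to 6, and so follows the split of the libraries, a structure of the samples. The 26 other splits that kept TNTProx1 4 to 6 on the same side had medians of 2131.5 unadjusted genes and 21.5 list members, against 384 and 1 in the 73 that parted them. For lists called, the medians were 16 and 17, against 20 in the real split. Without TNTProx1 4 to 6 the edgeR test called 0 genes, with 5116 genes at unadjusted p under 0.05 (10 libraries, TNTProx1 4 to 6 left out).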
